A study of Homo sapiens with 3 samples.

How the data were processed

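The authors deposited counts of ligated read pairs, as 4 tables per line with 1 count column per replicate. Per the submitters' processing notes, reads were processed with CASAVA 1.8 and positions refer to GRCh37 (hg19). The aligner and its settings were not given in the sources used here. Per the labels, fixation lasted 5 min and used formaldehyde at 2%, BT483 was lysed with trypsin, SUM44 and GM06990 with a dounce, and SUM44 was grown with estradiol. All 1077 captured HindIII fragments were used, of which 1075 had cis counts, and all count columns were read without normalisation. In the within-capture table of SUM44 the trans counts per captured fragment were 1.93 and 1.91 times those of its cis table in the replicates, against 1 in the other lines, so counts within the captured regions were left out of comparisons between lines. Both replicates of a line were summed for calls, ratios and profiles, and kept apart for spread and for the between-line test.

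Library composition was the share of contacts outside the captured region that fell within 5.0 Mb of it (near cis), elsewhere on its chromosome (far cis) or on other chromosomes (trans), with exact Clopper-Pearson 95% intervals. Calls used a negative binomial regression for each line and locus of the count of each pair of captured and target fragments, on a cubic spline of log10 distance with 4 knots and the log trans count of the captured fragment, which stands for its capture efficiency. The one-sided upper tail p was adjusted by Benjamini-Hochberg over the pairs of that line and locus, and pairs with an adjusted p of at most 0.01 and a count of at least 5 were called. The p of a call says that a pair stands above the distance background of that line; pairs are not replicates. Adjacent called target fragments were merged, and per locus and line the 5 with the highest observed over expected ratio were named, with the 5 highest and 5 lowest ratios per pair of lines and the 5 tallest trans windows per line. Overlap between lines was set beside 10000 seeded draws of fragments at like distances. As an alternative, counts were thinned at random to the shallowest line of the locus. Thinning was a single draw per line and locus, so a call lost with thinned counts may reflect that draw. These tests, thresholds, naming rules and a list of alternatives were chosen before the data were examined.

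Ratios between lines used fragments with at least 50 contacts in 1 of the lines, scaled to the near cis total of the locus, with exact conditional binomial 95% intervals, and counted those at 2-fold. Profiles were correlated as log2 observed over expected with a pseudocount of 1. Trans windows of 50 kb were named when over 5 times the median window of the region and line. The 50 kb windows that stood above the background in all lines were outside the naming rule. Genes near the loci had been listed beforehand, but contact with their promoter windows was not run, because the annotation used GRCh38.p14 positions and the counts GRCh37.

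The between-line test was not part of the design, which took each line as 1 pooled library; the tables held 2 replicate columns, which allowed a test with n = 2 per line. Counts were summed over the captured fragments of a locus, and each target fragment with at least 50 contacts in 1 line was tested with edgeR 4.0.16 by the quasi-likelihood F test, with the log of the count expected from the distance background of each replicate as offset. P-values were adjusted by Benjamini-Hochberg over the 3 risk loci, and separately over the other 3 regions, with a threshold of 0.05. The test was first fitted to each region alone with near cis totals, which gave 223 fragments that differed between BT483 and SUM44. The joint form with distance offsets was made the main one after those counts had been seen, because the lines differed in distance slope, and it gave 14. DESeq2 1.42.0 was run on the same counts and offsets. Shared controls were simulated 20 times from means without a difference between lines and the fitted dispersions, and recovery from counts with known changes. The controls were also split, with 1 GM06990 replicate for each breast line in the same joint fit, a setting chosen after the results had been seen.

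Trans segments joined windows over 5 times the median of a breast line, and not of GM06990, that lay within 1 Mb of each other, with at least 10 windows. Their folds are means over those windows only, so the choice of windows favours a difference from GM06990; the same levels were also taken over every window between the ends. Edges counted as those of a segment within 2 Mb of its end. A segment was given to 1 region when its fold was at least 2 times that of the next region, and to several when at least 4 regions were raised. Far cis contacts in bins of 1 Mb were compared with GM06990 after scaling to the far cis total of the region. Blocks of shared change joined fragments within 250 kb, at least 5 per block. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3.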

Results

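Capture Hi-C counted the physical contacts of 3 regions associated with breast cancer risk (9q31.2, 8q24.21 and 2q35) in 2 breast cancer lines and 1 lymphoblastoid line. The method ligates DNA ends that lie close together in fixed nuclei and then enriches, by hybridisation, the ligated pairs that contain a chosen region. BT483 derives from a primary invasive ductal carcinoma, SUM44 from a pleural effusion of a breast cancer, and GM06990 from B lymphocytes. The question posed by the series is which distant sequences contact the risk regions in breast cells. Each line was 1 sample holding 2 replicates whose counts were given in separate columns (n = 2 per line). Nothing said that the replicates were separate cultures, so the p-values below measure only the spread between these samples, which may be technical. Pairs were amplified without molecular identifiers, so intervals on counts cover counting error only.

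The captured region of 2q35 lay on chromosome 2 from 217609776 to 218362744 (GRCh37) and held 227 HindIII fragments. That of 8q24.21 lay on chromosome 8 from 127886760 to 128470692 with 192 fragments, and that of 9q31.2 on chromosome 9 from 110758376 to 111099364 with 100 fragments. Fragments of 3 further regions, on chromosome 3 from 82599410 to 82938789, on chromosome 16 from 73599933 to 74183980 and on chromosome 18 from 38494518 to 39252983, were captured too, and the labels did not state their role. Contacts that left the captured regions numbered 1860834 and 5867422 in the replicates of BT483, 2531103 and 4268868 in those of GM06990, and 3644109 and 3399064 in those of SUM44. No gene was assigned to a target window, because the annotation at hand used another genome build. As background, IGFBP5 lies on the centromeric side of 2q35, the transcription factor gene MYC and the non-coding gene PVT1 on the telomeric side of 8q24.21, and the transcription factor gene KLF4 on the centromeric side of 9q31.2.

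SUM44 kept a larger part of its contacts on the captured chromosome than the other lines did. Contacts within 5.0 Mb of the captured region made up 36.6% ± 1.22 of the contacts outside it in SUM44 (mean ± SD, n = 2), against 18.3% ± 2.61 in BT483 and 17.6% ± 7.11 in GM06990. Trans contacts, with other chromosomes, made up 43.6% ± 2.15 in SUM44, 67.0% ± 3.27 in BT483 and 66.1% ± 10.7 in GM06990. In these shares the replicates of GM06990 differed by more than those of the breast lines. Their near cis shares were 22.7% (exact Clopper-Pearson 95% interval 22.6 to 22.7) and 12.6% (12.6 to 12.6). The replicates of BT483 differed by more in the part that came from single captured regions. The chromosome 16 region held 28.0% and 13.7% of their contacts outside the capture, against 18.6% and 18.9% in GM06990 and 11.7% and 11.8% in SUM44. With 2 replicates per line, SUM44 stood above both replicates of each other line in near cis share, and no test of that difference was run.

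Contact counts fell with distance at every locus, and most steeply at 2q35. The slope of log10 count on log10 distance at 2q35 was -1.36 ± 0.000968 in SUM44, -1.16 ± 0.121 in BT483 and -1.11 ± 0.0786 in GM06990 (mean ± SD, n = 2). At 8q24.21 it was shallower in both breast lines, -0.645 ± 0.119 in BT483 and -0.685 ± 0.00536 in SUM44, than in GM06990, -0.895 ± 0.0298. At 9q31.2 it was -0.993 ± 0.129 in BT483, -0.923 ± 0.0521 in GM06990 and -1.11 ± 0.0213 in SUM44. Calls were set against a distance background fitted to each line and locus, a choice made before the data were examined. The differences in slope are why the between-line test took the background of each replicate and locus as offset.

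At 2q35, a single target fragment on the centromeric side was called above the distance background in both breast lines. In SUM44 the call ended when counts were thinned, in a single random draw. This fragment, on chromosome 2 from 217560727 to 217563272, was called with 4 captured fragments in BT483 and 2 in SUM44. Its strongest pair in each line, 672 kb away with the captured fragment from 218232201 to 218236450, had 31 contacts in BT483, 14.7 times the background (exact Poisson 95% interval 9.99 to 20.9), and 81 in SUM44, 13.2 times (10.5 to 16.4). Summed over all captured fragments and tested between lines with edgeR, its contacts were higher than in GM06990 by 0.99 on the log2 scale in BT483 (SE 0.15, adjusted p = 0.00016) and by 0.68 in SUM44 (SE 0.14, adjusted p = 0.000888). With counts thinned to the shallowest line, the strongest pair in SUM44 fell to 7.20 times (adjusted p = 1) and SUM44 lost every call at 2q35. The draw was not repeated, so this fall may reflect that draw. A threshold of 0.001 ended the calls of both lines. SUM44 had 1 further called target from 218375366 to 218376342, at 13.2 times the background (9.92 to 17.3), which ended with distance as the only covariate (adjusted p = 0.0512) and with thinned counts (adjusted p = 0.265). GM06990 had 0 called pairs at 2q35 under the negative binomial background, where 2857 pairs with at least 5 contacts had an unadjusted one-sided p under 0.05 and the smallest adjusted p was 0.0369. A Poisson background called 97 there.

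At 8q24.21, GM06990 had the most called pairs, 20, all with targets telomeric of the captured region, against 2 in BT483 and 4 in SUM44. Of these, 11 pairs joined 4 captured fragments to chromosome 8 from 128568986 to 128588131, with a strongest pair of 52 contacts, 20.8 times the background (15.5 to 27.2). Targets from 128745991 to 128756979 reached 20.2 times (15.3 to 26.2), from 128801732 to 128808278 reached 20.4 times (12.6 to 31.23), from 128565428 to 128568949 reached 17.8 times (13.0 to 23.9), and from 130562997 to 130566850, 2374 kb away, 26.9 times on 12 contacts (13.9 to 46.9). With distance as the only covariate the target from 128801732, which rests on 1 pair, lost its call (15.1 times, adjusted p = 0.386). With fragment length as a further covariate it was lost too (adjusted p = 0.0244), as were those from 128745991, 128565428 and 130562997 (lowest adjusted p = 0.0128), while that from 128568986 was called under both. A count minimum of 20 also ended the call from 130562997. In the edgeR test the fragment from 128568986 to 128570345 was lower than in GM06990 in both breast lines, with a log2 change of -1.01 in BT483 (SE 0.17, adjusted p = 0.000385) and -1.25 in SUM44 (SE 0.16, adjusted p = 9.13e-06). The target from 128745991 changed by -0.64 in BT483 (SE 0.17, adjusted p = 0.0146) and by -1.22 in SUM44 (SE 0.17, adjusted p = 1.38e-05), and that from 128801732 by -0.68 (SE 0.19, adjusted p = 0.0181) and -1.59 (SE 0.19, adjusted p = 3.12e-06). The target from 130562997 changed by -0.73 in BT483 (adjusted p = 0.0142) and by -0.72 in SUM44 (adjusted p = 0.00519).

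The breast lines had other called targets of 8q24.21. In BT483 these were chromosome 8 from 128740188 to 128745990, at 11.9 times the background (8.13 to 16.8), and from 128470693 to 128472759, next to the captured region, at 7.31 times (6.55 to 8.14). The second lies 6.63 kb from its captured fragment, where the background was unstable: the ratio was 2.37 with distance only (adjusted p = 1), the replicates alone gave 6.05 and 5.60, and GM06990 had 0.20 summed but 2.31 and 1.87 in its replicates. With thinned counts both calls in BT483 ended (adjusted p = 0.0107 and 0.0488). The first did not differ detectably between BT483 and GM06990 (-0.13, SE 0.17, adjusted p = 0.698). In SUM44 they were 128644931 to 128649270, at 10.9 times (7.86 to 14.7), and 130547079 to 130549444, at 20.6 times (11.6 to 34.1), and both calls ended with distance only (lowest adjusted p = 0.0267) and with thinned counts (0.215). Neither differed detectably between SUM44 and GM06990 in the edgeR test (lowest adjusted p = 0.292). That test sums each target over all captured fragments of the locus, so a difference in the called pairs was not tested. Their call in 1 line alone shows no difference between lines.

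At 9q31.2, both breast lines contacted a stretch centromeric of the captured region, mostly from a single captured fragment, 111033955 to 111035778. In BT483 the targets were chromosome 9 from 110238956 to 110255868, at 15.8 times the background (10.2 to 23.3), and from 110275212 to 110280502, at 10.7 times (6.37 to 16.98). In SUM44 they were 110183823 to 110207271, at 13.9 times (9.60 to 19.4), and 110244650 to 110255868, at 11.0 times (7.43 to 15.7). The target from 110275212 in BT483 lost its call with distance only (adjusted p = 0.0527) and with a count minimum of 20, and that from 110244650 in SUM44 with thinned counts (adjusted p = 0.136). GM06990 had 0 called pairs under the negative binomial background, with 1343 at an unadjusted p under 0.05 and at least 5 contacts, a smallest adjusted p of 1, and 4 calls under a Poisson background. The lowest adjusted p of any called target of 9q31.2 in the edgeR comparisons between lines was 0.114, so no difference was detectable in contacts summed over all captured fragments. A difference in the called pairs, mostly from a single captured fragment, was not tested.

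Across the 3 risk loci 42 pairs were called among 1567543 tested per line, and 0 among 1656732 per line at the other captured regions, where the Poisson background called 246 in BT483, 36 in GM06990 and 196 in SUM44. Every one of the 42 stood above its background in both replicates, 41 of them with an unadjusted p under 0.01 in each. The calls were made on the sum of the same replicates, so this was close to given by the selection and is no separate support. BT483 and SUM44 shared 1 called target fragment at 2q35 and 1 at 9q31.2; random fragments at like distances shared 0.0207 and 0.156 on average, and 207 and 1499 of 10000 draws shared as many. The numbers rest on both replicates: without replicate 2 the calls in BT483, GM06990 and SUM44 were 0, 0 and 0 at 2q35, 1, 0 and 0 at 8q24.21, and 0, 0 and 5 at 9q31.2, and without replicate 1 they were 3, 0 and 0, then 0, 6 and 0, then 3, 0 and 1. In counts simulated from the fitted backgrounds of the risk loci, pairs with an expected count of at least 1 were raised. Of those raised 10-fold 17% to 46% were called, and of those raised 20-fold 40% to 82%, so a pair that was not called can still be a contact. Recovery of pairs with a lower expected count, and at the other captured regions, was not simulated.

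**Figure D1:**
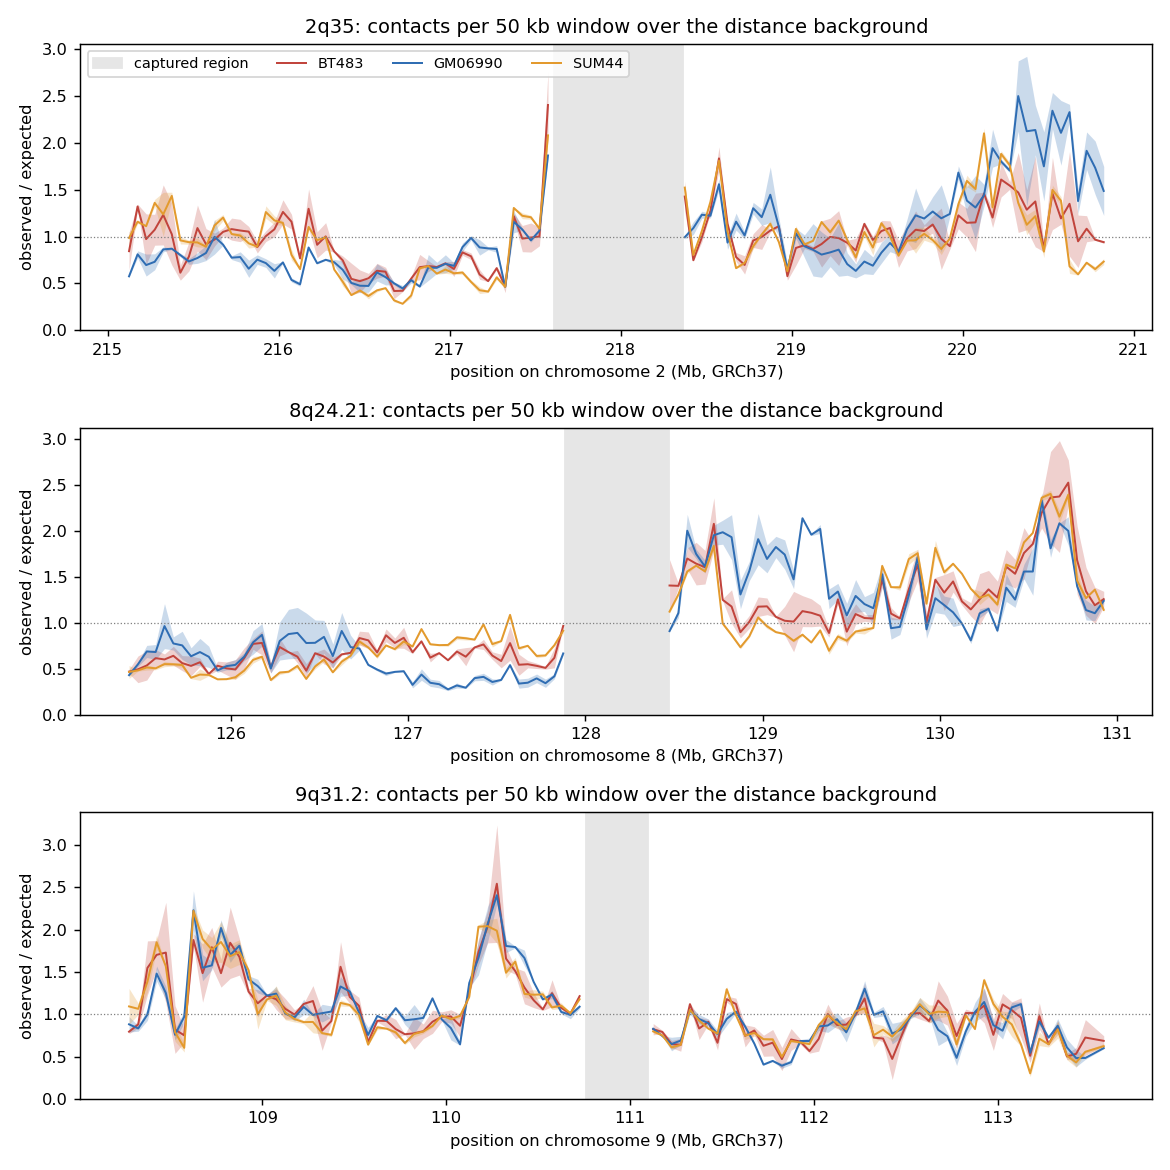
Contacts of the 3 risk loci in 50 kb windows, as the observed count over the count expected from the distance background (vertical axis) by position on GRCh37 in Mb (horizontal axis), for BT483, GM06990 and SUM44; lines are means and bands 1 SD of 2 replicates, and grey marks the captured region. All 3 lines rise together in the 8q24.21 window that starts at 130550001 (2.20, 2.33 and 2.36 times) and the 9q31.2 window that starts at 110200001 (2.04, 2.07 and 2.04 times).

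In windows of 50 kb, each locus had stretches that stood above the distance background in all 3 lines (windows picked after their values were seen, by the lowest of the 3 lines). At 2q35 the window from 217550001 to 217600000 held 2.40 ± 0.359 times the background in BT483, 1.86 ± 0.0343 in GM06990 and 2.08 ± 0.0217 in SUM44 (mean ± SD, n = 2). At 8q24.21 the window from 130550001 to 130600000 held 2.20 ± 0.166, 2.33 ± 0.0827 and 2.36 ± 0.0298 times the background in the same order. At 9q31.2 the window from 110200001 to 110250000 held 2.04 ± 0.192, 2.07 ± 0.207 and 2.04 ± 0.0721 times. On chromosome 16 the window from 72150001 to 72200000 held 2.91 ± 0.0418, 2.54 ± 0.0792 and 3.41 ± 0.0387 times.

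Among the 3 risk loci, most of the fragments that differed between the breast lines and the lymphoblastoid line lay at 8q24.21, on either side of the captured region. That locus also held 2727 of the 5466 fragments tested. Of 343 tested fragments on its centromeric side, chromosome 8 from 126754896 to 127886759, 205 had higher contact in both breast lines than in GM06990, with median log2 changes over all 343 of 0.83 in BT483 and 1.05 in SUM44. On the telomeric side, from 128565428 to 129594917, 115 of 296 fragments were lower in both and 3 higher in both, with medians of -0.46 and -0.72. Each side also held blocks of the opposite direction, with fewer such fragments. Telomeric ones had 15 of 85 (overlapping this stretch), 26 of 486 and 8 of 146 fragments higher in both. Centromeric ones had 15 of 71, 8 of 78 and 5 of 37 lower in both. At 2q35, 26 of 91 fragments from 220285999 to 221017244 were lower in both (medians -0.99 and -1.01), and at 9q31.2, 19 of 116 from 111523998 to 111880134 were higher in both (0.46 and 0.52). A nearer stretch of 2q35, from 218385700 to 218938900, had 28 of 148 fragments lower in both and 7 higher in both, with medians of -0.25 and -0.25; it overlaps a stretch from 218362745 to 218640506 with 11 of 82 fragments higher in both. Its median in SUM44 turned positive (0.01 to 1.39) under every scaling that left the distance background in. Relative to the median of all fragments it stayed lower with trans totals (-0.18) and with near cis totals after the count filter (-0.08), and lay 0.01 to 0.11 above with the others, near cis totals without the filter among them (0.10). The other 4 stretches given with medians kept their direction in both lines under every setting, with 1 exception. The telomeric 8q24.21 stretch in SUM44 turned to 0.50 when each region was scaled to its trans total. That scaling raised the median of all fragments from 0.09 to 1.57. Relative to that median the stretch stood at -1.07. All these stretches were picked under the main setting and every setting reused the same counts, so a kept direction is no independent support.

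The size of these changes was less stable than their direction. With each region fitted alone, the centromeric 8q24.21 stretch in BT483 fell to 0.32 (TMM factors and DESeq2 size factors) and 0.22 (trans total, 0.34 above the median of all fragments) and in SUM44 to 0.63 (TMM factors and DESeq2 size factors). The telomeric stretch moved to -0.98 (TMM factors), -0.99 (DESeq2 size factors) and -1.13 (trans total) in BT483 and to -1.11 in SUM44 (TMM factors and DESeq2 size factors). The 9q31.2 stretch fell in BT483 to 0.17 without BT483 replicate 2 and 0.20 with joint TMM factors, and in SUM44 to 0.30 with joint TMM factors, where it exceeded the median of all fragments by only 0.08 and 0.04. With trans totals in SUM44, the centromeric 8q24.21, far 2q35 and 9q31.2 stretches stood at 2.26, -0.04 and 2.14. Relative to the median of all fragments these are 0.69, -1.61 and 0.57. The nearer 2q35 stretch in BT483 moved to -1.18 with joint TMM factors and to between -0.38 and -0.77 with each region fitted alone.

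**Figure D2:**
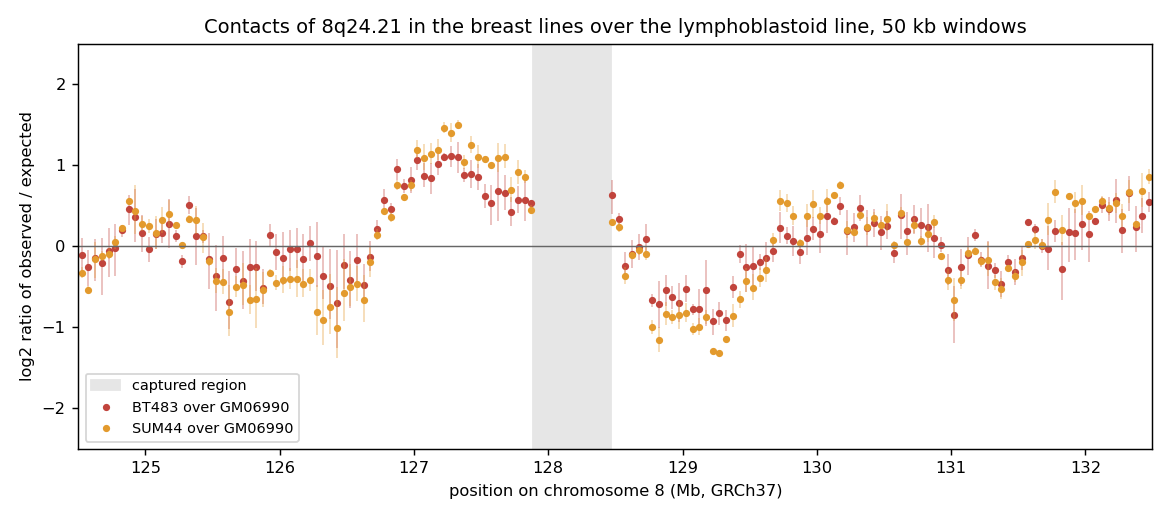
Contacts of 8q24.21 in BT483 and SUM44 relative to GM06990, as the log2 ratio of observed over expected contacts (vertical axis) in 50 kb windows along chromosome 8 in Mb, GRCh37 (horizontal axis); points compare means of 2 replicates, vertical bars span the 4 ratios of single replicates, and grey marks the captured region. Points of both lines lie above 0 between 126754896 and 127886759, where the median changes were 0.83 and 1.05, and mostly below 0 between 128565428 and 129594917.

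Over the 5466 target fragments tested at the 3 risk loci, BT483 differed from GM06990 at 692 (414 higher, 278 lower) and SUM44 at 1326 (750 higher, 576 lower; edgeR, adjusted p under 0.05). Tested fragments numbered 1733 at 2q35, 2727 at 8q24.21 and 1006 at 9q31.2. BT483 differed at 178, 457 and 57 of them, and SUM44 at 416, 809 and 101. Tested fragments of the captured regions on chromosomes 3, 16 and 18 numbered 796, 1507 and 2279. BT483 differed at 31, 398 and 102 of them and SUM44 at 39, 189 and 163, so differences were not limited to the risk loci. The largest changes were in BT483 and SUM44 alike at a 14 bp fragment on chromosome 8 from 127008585 to 127008598 (3.87, SE 0.67, adjusted p = 0.000605, and 4.13, SE 0.62, adjusted p = 2.81e-05), which had only 2 contacts in GM06990. The lowest were on chromosome 2, from 221006902 to 221017244 in BT483 (-2.29, SE 0.48, adjusted p = 0.0032) and from 220636169 to 220642138 in SUM44 (-2.47, SE 0.35, adjusted p = 1.9e-05). DESeq2 called 230 and 668 fragments.

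The counts and their split depended on the scaling and on single libraries. For BT483 against GM06990 the numbers higher and lower became 641 and 275 when scaled to the near cis total with the distance background left in, and, with each region fitted alone, 665 and 256 (near cis total), 771 and 262 (the same without a count filter), 254 and 413 (TMM) and 40 and 242 (DESeq2 size factors); with joint TMM factors 1352 differed, and scaled to trans totals 0 did, with a median change of -0.11. For SUM44 against GM06990 they became 877 and 319 with joint TMM factors and, with each region fitted alone, 926 and 1226 (no count filter), 589 and 735 (TMM), 208 and 368 (DESeq2 size factors) and 2677 and 0 (trans total). Leaving out 1 library changed 692 to 1063 (BT483 replicate 1), 366 (BT483 replicate 2), 312 (GM06990 replicate 1) or 117 (GM06990 replicate 2), and 1326 to 601 (SUM44 replicate 1), 611 (SUM44 replicate 2) or 636 (GM06990 replicate 2).

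Of the fragments that differed from GM06990, 592 did so in the same direction in BT483 and SUM44 (352 higher, 240 lower) and 0 in opposite directions. By locus these were 140 of 1733 tested fragments of 2q35, 419 of 2727 of 8q24.21 and 33 of 1006 of 9q31.2. Independent lists of the same sizes would share 56.8 higher and 29.3 lower. Both comparisons used the same GM06990 libraries. In 20 simulations without a difference between lines, the log2 changes had a covariance of 0.0632 (r = 0.602), against 0.3501 (r = 0.814) observed. Each simulation shared 0 calls, but counts without a difference are bound to give few calls to share. That 0 is therefore no chance level for the 592. A split of the controls leaves 1 GM06990 replicate per breast line. With replicate 1 for BT483 and replicate 2 for SUM44 the covariance was 0.275, and with the reverse 0.296, where simulated counts gave 0.000266 and 0.000165. The first split shared 81 fragments (49 higher, 32 lower), where independent lists would share 6.17 and 3.37. The reverse shared 189 (105 higher, 84 lower), where independent lists would share 9.90 and 7.89. The simulated counts shared 0, which for the same reason is no chance level. The covariance therefore did not rest on shared libraries alone, but part of the excess of 592 may come from the shared controls, and both replicates are of 1 line. The shared count fell to 295 without BT483 replicate 2, 291 without GM06990 replicate 1, 106 without GM06990 replicate 2, 296 without SUM44 replicate 1 and 295 without SUM44 replicate 2. The split of higher and lower moved to 537 and 163 with joint TMM factors, to 163 and 344 with each region fitted alone with TMM factors and to 37 and 210 with DESeq2 size factors.

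The breast lines were close to each other once the distance background of each library was removed. BT483 and SUM44 differed at 14 of 5466 fragments of the risk loci, all at 8q24.21 (3 higher and 11 lower in BT483). At 2q35 and 9q31.2 edgeR and DESeq2 each called 0, with 245 of 1733 and 55 of 1006 tested fragments at an unadjusted edgeR p under 0.05. At 2q35 that share is well above 0.05, so differences too small to be called there are not excluded. Among the 14, the neighbouring fragments from 131846563 to 131851805 and from 131851806 to 131852415 were lower in BT483 (-1.53, SE 0.32, adjusted p = 0.0325, and -2.44, SE 0.36, adjusted p = 0.00105). The fragment from 128801732 to 128808278, a called target in GM06990, was higher in BT483 than in SUM44 by 0.91 (SE 0.19, adjusted p = 0.0325). At the captured regions on chromosomes 3, 16 and 18 the lines differed at 6, 47 and 25 fragments. In simulated data with these library sizes, 68% of fragments changed 2-fold and 96% of those changed 4-fold were recovered for this comparison.

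This closeness depended on removing the distance background and on all libraries. The numbers higher and lower in BT483 were 42 and 20 scaled to the near cis total and 34 and 397 with joint TMM factors; with each region fitted alone they were 172 and 51 (near cis total), 947 and 73 (no count filter), 70 and 73 (TMM), 0 and 9 (DESeq2 size factors) and 0 and 3749 (trans total, with a median change of -1.66). Without BT483 replicate 1 the 14 became 223, without BT483 replicate 2 it became 93, without SUM44 replicate 1 it became 3 and without SUM44 replicate 2 it became 4.

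The contact ratios fixed in the design, scaled to the near cis total of the locus with no test, differed from GM06990 at a larger share of fragments at 8q24.21 than at the other risk loci. BT483 had at least 2 times the contacts of GM06990 at 400 of 2495 fragments of 8q24.21 and at most 0.5 times at 57, against 45 and 40 of 985 at 2q35 and 41 and 20 of 805 at 9q31.2. SUM44 had 461 higher and 117 lower of 2628 at 8q24.21, 78 and 153 of 1733 at 2q35, and 35 and 58 of 998 at 9q31.2. BT483 against SUM44 gave 128 and 3 of 1690 at 2q35, 83 and 16 of 2727 at 8q24.21, and 12 and 4 of 992 at 9q31.2. These ratios also carry the differences in distance slope between the lines.

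Among single fragments, the highest ratio was at the same 14 bp fragment of 8q24.21, 15.97 in BT483 over GM06990 (56 contacts against 2; exact conditional binomial 95% interval 4.22 to 135) and 19.8 in SUM44 over GM06990 (111 against 2; 5.36 to 166). The next 4 in BT483 ranged from 7.99 to 10.6 and in SUM44 from 8.94 to 15.7, all at 8q24.21 and on 2 to 4 contacts in GM06990. Placement of reads in a fragment as short as 14 bp was not tested. The lowest were 0.211 in BT483 on chromosome 9 from 112379589 to 112380407 (15 against 61; 0.111 to 0.376) and 0.122 in SUM44 on chromosome 2 from 220636169 to 220642138 (26 against 76; 0.0750 to 0.193), and the other 4 lowest in SUM44, 0.133 to 0.156, all lay between 220608726 and 220975486. Between the breast lines the highest was 4.64 on chromosome 8 from 123179055 to 123181490 (61 against 21; 2.78 to 8.02) and the lowest 0.204 from 131851806 to 131852415 (0.115 to 0.339).

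Summed over the 3 risk loci the ratios were 486 higher and 117 lower for BT483 over GM06990, 574 and 328 for SUM44 over GM06990, and 223 and 23 for BT483 over SUM44. Scaled to the whole library they were 1364 and 202, 3838 and 12, and 4 and 2480; scaled to trans totals, 370 and 150, 4589 and 5, and 0 and 4717; with a minimum of 200 contacts, 81 and 74, 253 and 136, and 2 and 11. Without BT483 replicate 2, BT483 over GM06990 gave 110 higher and 282 lower and BT483 over SUM44 154 and 211.

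With the distance trend removed, the contact profiles of the breast lines resembled each other more than either resembled GM06990 at each locus with all replicates. Without BT483 replicate 2 this held by Pearson's r at 8q24.21 alone. At 2q35 Pearson's r across 3041 fragments was 0.750 between BT483 and SUM44 (Spearman's rho 0.652), 0.647 between BT483 and GM06990 (0.538) and 0.570 between SUM44 and GM06990 (0.433). At 8q24.21, across 3033 fragments, r was 0.864 (0.818), 0.778 (0.749) and 0.692 (0.635), and at 9q31.2, across 2949, 0.787 (0.801), 0.489 (0.443) and 0.504 (0.432), in the same order. These are correlations across fragments, which are not independent replicates, and the differences were not tested. Replicates of 1 line correlated at 0.471, 0.740 and 0.465 in BT483, 0.741, 0.831 and 0.672 in GM06990 and 0.860, 0.934 and 0.730 in SUM44 at 2q35, 8q24.21 and 9q31.2. The order at 2q35 turned without BT483 replicate 2, where r was 0.451 between the breast lines and 0.458 between BT483 and GM06990. Spearman's rho turned there too, at 0.393 and 0.408. At 9q31.2 r turned as well, to 0.490 between the breast lines, below the 0.504 of SUM44 and GM06990. Spearman's rho kept its order at 9q31.2, with 0.487 between the breast lines, 0.432 between SUM44 and GM06990 and 0.409 between BT483 and GM06990.

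Trans contacts were concentrated on few places in the breast lines, above all in SUM44. Summed over the 6 captured regions, 4751 pairs of a region and a 50 kb window exceeded 5 times the median window in SUM44, 1547 in BT483 and 273 in GM06990, at 2649, 981 and 80 distinct windows. Over 10 times the median they numbered 986, 107 and 27. The count in GM06990 rose to 1038 without its replicate 2 and to 458 without its replicate 1. Counting noise passes the cut more easily where the median window holds few contacts. For the chromosome 3 region the median was 2 in SUM44, 3 in BT483 and 4 in GM06990, with 691, 522 and 52 windows over. Without replicate 2 GM06990 had a median of 1 there and 505 windows over. At 2q35, with medians of 13, 14 and 20 in the same order, windows over numbered 1194, 239 and 33. The tallest windows in GM06990 were on chromosome 21 from 10700001 to 10750000 with the chromosome 18 region (20.9 times the median, exact Poisson 95% interval 18.6 to 23.3) and with the chromosome 3 region (20.2), on chromosome 19 from 24500001 to 24550000 with the chromosome 18 region (16.9) and with 9q31.2 (15.5), and on chromosome 10 from 42400001 to 42450000 with the chromosome 3 region (16.8). The same window of chromosome 10 led in BT483, with the regions on chromosomes 3 (41.3; 34.4 to 49.3), 16 (29.8) and 18 (29.4), beside chromosome 12 from 34800001 to 34850000 (41.0) and chromosome 21 from 10700001 (33.0).

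In SUM44 the tallest trans windows lay elsewhere. They were chromosome 6 from 300001 to 350000 with the chromosome 16 region (42.4; 36.9 to 48.5), the next window from 350001 (37.8), chromosome 11 from 54800001 to 54850000 (37.8; 34.3 to 41.6) and from 80400001 to 80450000 (37.3; 33.8 to 41.1) with 8q24.21, and chromosome 8 from 36600001 to 36650000 with the chromosome 18 region (37.4; 33.0 to 42.2). Trans segments were averaged over windows that were over 5 times the median in SUM44 and not in GM06990, a choice that favours a difference. Of the 65 segments of both breast lines, 17 were raised from 1 captured region, 5 from 4 or more, and 43 (20 in BT483, 23 in SUM44) fell between. In 30 of these 43 the median of the other regions was at least 1.5 times its GM06990 level. 8q24.21 contacted chromosome 6 from 61850001 to 73000000 at 6.87 ± 0.597 times the mean trans window in SUM44 (n = 2), against 1.04 ± 0.0254 in GM06990. 2q35 contacted chromosome 7 from 147000001 to 152450000 at 7.06 ± 0.649 times in SUM44, against 1.36 ± 0.0179 in GM06990. The chromosome 18 region contacted chromosome 5 from 1650001 to 18150000 at 6.02 ± 0.486 times and chromosome 8 from 100750001 to 121100000 at 7.19 ± 0.589 times in SUM44, against 1.49 ± 0.0143 and 1.35 ± 0.0427 in GM06990.

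**Figure D3:**
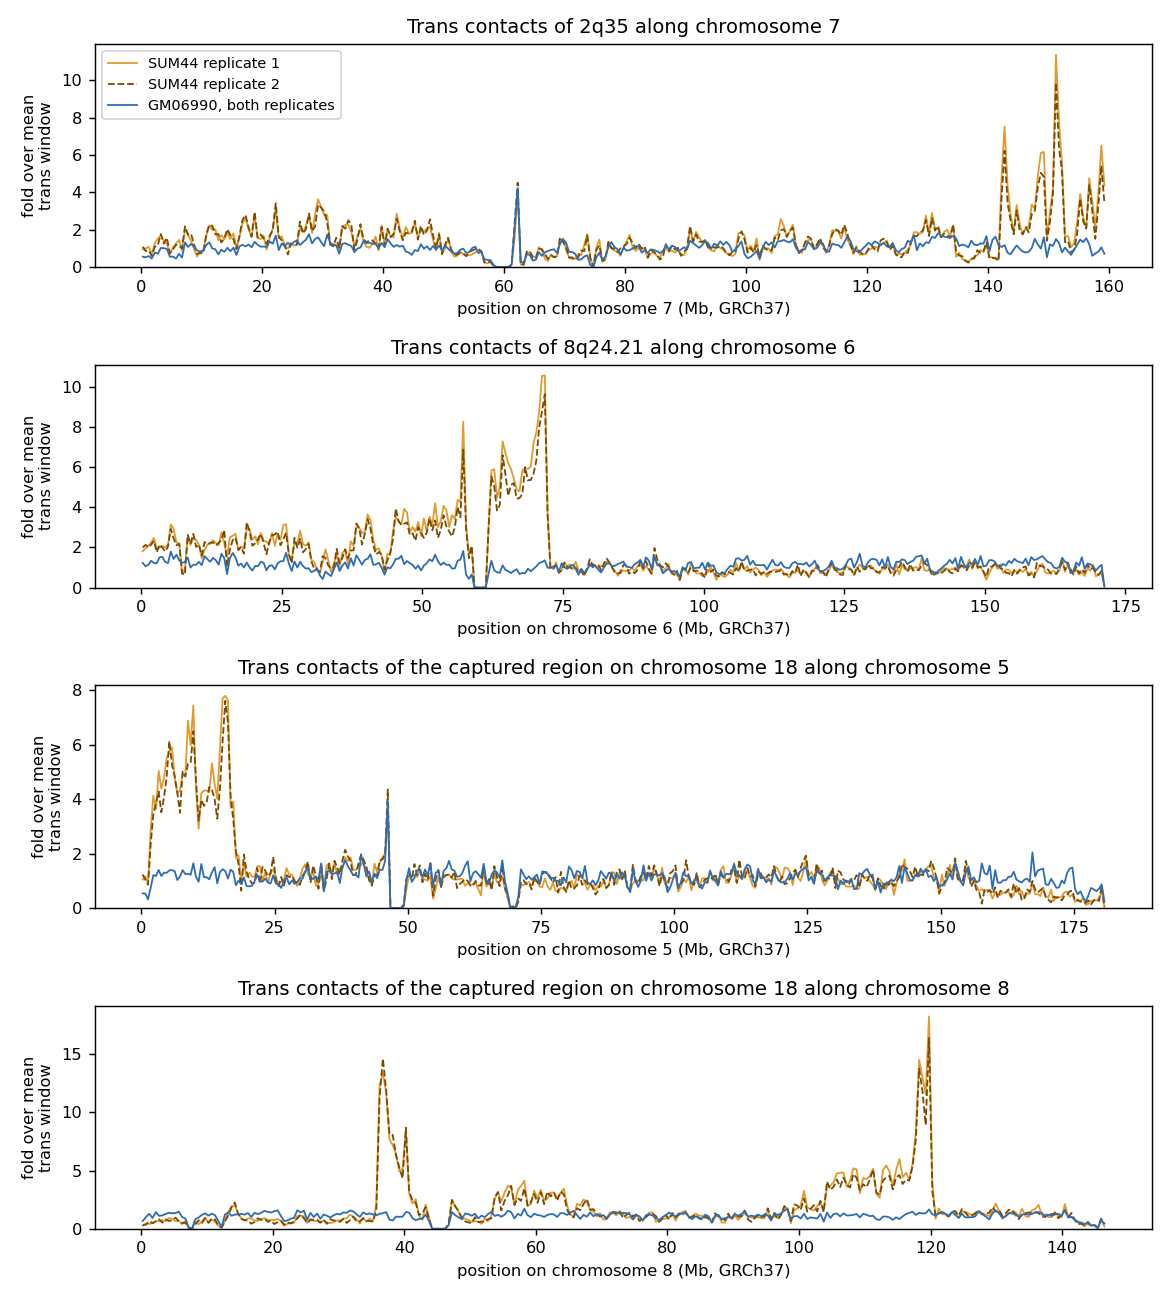
Trans contacts of 2q35 along chromosome 7, of 8q24.21 along chromosome 6 and of the captured region on chromosome 18 along chromosomes 5 and 8, as the fold over the mean trans window of the library and region (vertical axis) by position in Mb, GRCh37 (horizontal axis); the lines are the 2 replicates of SUM44 and the sum of both replicates of GM06990. Both SUM44 replicates rise over the same stretches, at 7.06, 6.87, 6.02 and 7.19 times the mean in the segments named in the text, where GM06990 stays between 1.04 and 1.49.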

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

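The tests of far cis contacts, of trans segments (except the edge test with all windows) and of the differences shared by the breast lines were chosen after results had been seen.

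BT483 and SUM44 differed from GM06990 in the same direction at 592 fragments of the 3 risk loci. Most of them lay at 8q24.21, which held 2727 of the 5466 fragments tested. For these differences 3 explanations were weighed. Copy number of the target segment would raise or lower trans contacts too. In the 158 windows concerned, pooled over loci, median cis shifts were 0.48 and 0.52 on the log2 scale in BT483 and SUM44. The median trans shift, relative to the trans total of the locus, was 0.0223 in BT483 (bootstrap 95% interval -0.0446 to 0.0858) and -0.0554 in SUM44. Copy number is thus unlikely to be the main source over the pooled windows, but single loci differed. Cis and trans ratios over GM06990 in 50 kb windows correlated at 0.45, 0.084 and 0.21 in BT483 at 2q35, 8q24.21 and 9q31.2. In SUM44 the values were 0.10, -0.54 and 0.35. Dividing by trans contact cut the 2q35 windows higher 2-fold in BT483 from 9 to 2, but not those of the other loci. Lysis with trypsin in BT483 and by dounce in the other lines could not give the difference of SUM44 from GM06990, both lysed by dounce, at 1326 fragments; BT483 and SUM44 themselves differed at 14, a count that depends on the scaling. Cell type could give such a pattern, and so could anything else that sets the only lymphoblastoid line apart, so 1 such line cannot tell them apart. Part of the excess may come from the shared controls, whose simulated covariance was 0.0632 against 0.3501 observed, though 0.275 and 0.296 remained with a separate GM06990 replicate for each breast line.

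In BT483 and SUM44, 17 trans segments were raised from 1 captured region, 6 and 11 of them, with a median fold of 5.37 and 5.80. More copies of the target segment would raise all regions, but the median of the other regions stayed under 1.5 times its GM06990 level in 17 of 17 and each single one in 16 of 17 (on chromosome 12 from 118850001 in BT483 the chromosome 3 region reached 2.34 against 1.48) or, over every window between the ends, in 14 of 17, a test eased by the choice of segments with 1 leading region, and one that leaves out 43 segments between the kinds, where the other regions rose at least 1.5 times in 30. Repeated or hard to map sequence would be raised in GM06990 too, which stayed under 0.5 times the breast line's level in 17 of 17, also over every window between the ends (17). Windows high in GM06990 had been set aside before segments were built, so this was largely given by the selection and does not test that explanation. A junction that joins the region to the segment should give a sharp edge, placed in replicate 1 and tested in replicate 2: 3 of 8 pairs of region and chromosome passed in the form written first, where 4 of 8 edges fell on stretches almost without GM06990 contacts, and 7 of 8 with such sequence gaps left out, a form chosen afterwards. Some of these edges lay elsewhere on the chromosome, as on chromosome 8 at the segment raised from several regions. Within 2 Mb of the segment itself, a limit added afterwards, 2 of 8 passed with all windows and 5 of 8 with gaps left out. The chromosomes were picked by segments built from both replicates, with windows high in GM06990 set aside. Replicate 2 and GM06990 are therefore not independent tests of an edge, and a junction stays open.

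In 5 trans segments, 4 or more captured regions were raised together: chromosome 8 from 36950001 to 38050000 in BT483, and in SUM44 chromosome 8 from 35950001 to 41700000, chromosome 1 from 93650001 to 103700000, chromosome 11 from 72650001 to 80700000 and chromosome 16 from 52700001 to 56050000. GM06990 stayed under 0.5 times the breast line's level in 5 of 5, also over every window between the ends (5). Windows high in GM06990 had been set aside here too, so this was largely given by the selection. It does not test whether repeated or hard to map sequence is the source. More copies of the target segment should also raise far cis contacts of a captured region on the same chromosome. That ratio over GM06990 was 5.76 on chromosome 8 in BT483 and 2.76 in SUM44, but 0.719 on chromosome 16 in SUM44, so more copies may hold for chromosome 8 and were not shown for chromosome 16.

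BT483 had 6.10 times the far cis contacts of GM06990 between 8q24.21 and chromosome 8 from 37000001 to 38000000 (conditional binomial 95% interval 5.68 to 6.57, after scaling to the far cis total of the region). SUM44 had 5.23 times those between 8q24.21 and chromosome 8 from 36000001 to 37000000 (4.78 to 5.74). SUM44 had 4.46 times those between 9q31.2 and chromosome 9 from 130000001 to 131000000 (3.93 to 5.09), and BT483 3.37 times (2.95 to 3.86). SUM44 had 3.70 times those between 2q35 and chromosome 2 from 226000001 to 227000000 (3.57 to 3.83).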

How the results depend on the processing

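The between-line edgeR tests and their settings, the split of the controls and the covariate of fragment length were chosen after the data had been seen. So were the edge tests with sequence gaps left out, the limit of 2 Mb for edges and the runs without 1 replicate. The other alternatives were fixed before. Calls moved with the threshold and the spread allowed about the background. In BT483, GM06990 and SUM44, an adjusted p of 0.05 gave 7, 1 and 18 pairs at 2q35, with 12 in BT483 and 39 in GM06990 at 8q24.21, 10 in BT483 and 21 in SUM44 at 9q31.2, and 1 in SUM44 at the other regions. An adjusted p of 0.001 gave 0 in BT483 and 0 in SUM44 at 2q35, 1, 5 and 0 at 8q24.21, and 3 in BT483 at 9q31.2. A Poisson spread gave 240, 97 and 3107 at 2q35, 152, 1191 and 1013 at 8q24.21, 26, 4 and 252 at 9q31.2, and 246, 36 and 196 at the other regions. Distance only gave 7 in BT483 and 5 in SUM44 at 2q35, 1, 10 and 0 at 8q24.21, and 3 in BT483 at 9q31.2. Counts thinned in a single draw gave 0 in SUM44 at 2q35, 0 in BT483 and 0 in SUM44 at 8q24.21, and 2 in SUM44 at 9q31.2. Fragment length as covariate gave 5 in BT483 and 11 in GM06990 at 8q24.21. A count minimum of 20 gave 2 in SUM44 at 8q24.21 and 3 in BT483 at 9q31.2. Counting neighbouring fragments, BT483 and GM06990 shared 1 target at 8q24.21 and BT483 and SUM44 shared 2 at 9q31.2. Without 1 replicate, calls ranged from 0 to 3 in BT483 and 0 to 0 in SUM44 at 2q35, from 0 to 1, 0 to 6 and 0 to 0 at 8q24.21, from 0 to 3 in BT483 and 1 to 5 in SUM44 at 9q31.2, and from 0 to 1 in BT483 at the other regions.

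Planned ratios gave 1566, 3850 and 2484 fragments scaled to the whole library (BT483 over GM06990, SUM44 over GM06990, BT483 over SUM44), 4594 and 4717 in the last 2 scaled to trans totals, 155, 389 and 13 with a minimum of 200, and 392 to 696 in the first without 1 replicate. Profiles without removal of the distance trend correlated at 0.901, 0.876 and 0.925 at 2q35, 0.918, 0.890 and 0.953 at 8q24.21 and 0.856, 0.866 and 0.9498 at 9q31.2 (BT483 with GM06990, SUM44 with GM06990, BT483 with SUM44). A pseudocount of 0.5 gave 0.4997 between SUM44 and GM06990 at 9q31.2. Without 1 replicate r ranged over 0.458 to 0.624, 0.504 to 0.548 and 0.451 to 0.741 at 2q35, 0.666 to 0.767, 0.616 to 0.701 and 0.760 to 0.850 at 8q24.21, and 0.428 to 0.453, 0.460 to 0.473 and 0.490 to 0.772 at 9q31.2; the low values between the breast lines, 0.451 and 0.490, came without BT483 replicate 2. Trans windows over 10 times the median numbered 107, 27 and 986, and GM06990 had 458 over 5 times without replicate 1 and 1038 without replicate 2.

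For the edgeR test, in the order of the ratios, DESeq2 gave 230, 668 and 2 fragments, with 202 shared by the breast lines. Joint TMM factors gave 1352 and 431 in the first and last, and near cis totals 62 in the last. With each region fitted alone, near cis totals gave 223 in the last, no count filter 2152 and 1020 in the last 2, TMM factors 143 in the last, DESeq2 size factors 282, 576 and 9 with 247 shared, and trans totals 0, 2677 and 3749 with 0 shared. The form fitted first was that with 223, and the form with distance offsets (14) was made the main one afterwards. A replicate block gave 637, 1285 and 20; deviations of the replicates correlated at -0.065, 0.055 and -0.019 between lines, so replicate numbers were not treated as pairs. Without 1 replicate the counts ranged from 117 to 1063, from 601 to 894 and from 3 to 223, and those shared from 106 to 875. With 1 GM06990 replicate for each breast line the shared count was 81 (replicate 1 for BT483, 2 for SUM44) and 189 (the reverse). The median of the 2q35 stretch from 218385700 to 218938900 in SUM44 turned positive, at 0.0089 (near cis total), 0.27 (joint TMM), 0.0085, 0.0084, 1.39, 0.10 and 0.088 (each region alone: near cis total, no count filter, trans total, TMM, DESeq2 size factors), and so did that of the telomeric 8q24.21 stretch, at 0.50 (trans total). The trans total put the median of all fragments at 1.57, and both stretches stayed below it. In SUM44 the trans total also turned the stretches from 72902358 and 71275103 on chromosome 16 to 0.81 and 1.38 and that from 217085406 at 2q35 to 0.60, and joint TMM turned that from 72215981 on chromosome 16 to -0.22. Edges with sequence gaps left out passed in 7 pairs, 5 of them within 2 Mb of the segment. The cause was not tested for results that moved. The promoter windows with their 3 alternatives, and calls from the coarser table, which covers another range, were not run.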

Other observations

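The tests of the segments and stretches in this part were chosen after results had been seen. The only exception was the edge test with all windows, without its limit of 2 Mb to a segment. The captured region on chromosome 16 differed from GM06990 in BT483 more widely than any other captured region, at 398 of 1507 fragments or 26.4% (edgeR, Benjamini-Hochberg), an order lost with joint TMM factors (15.3%, against 30.6% at 8q24.21) and with trans totals (0.0664%). This region held 28.0% and 13.7% of the contacts outside the capture in the BT483 replicates, whose profiles there correlated at 0.804. Contacts were lower in both breast lines from 72902358 to 73227918, where 37 of 75 fragments were lower in both (median log2 -1.04 in BT483 and -0.70 in SUM44), and higher from 72215981 to 72836711, at 37 of 211 (0.50 and 0.30). Further away, from 71275103 to 72066151, 23 of 163 were lower (-1.08 and -0.54). At 2q35, 11 of 95 fragments from 214868805 to 215311119 were higher in both breast lines (0.71 and 1.104), and 17 of 76 from 217085406 to 217331907 were lower (-0.34 and -0.83). These 5 stretches kept their direction in BT483 under every setting, which is no independent support, since they were picked under the main setting from the same counts. In SUM44 the lower ones turned positive with trans totals, where the region medians rose to 1.77 on chromosome 16 and 1.41 at 2q35, and the higher one on chromosome 16 turned to -0.22 with joint TMM factors, where its region median was -0.50.

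In SUM44, the trans contacts of 2q35 rose along chromosome 7 at 142100001, by a step of 10.9 in replicate 1 and 9.95 in replicate 2, against 0.905 in GM06990. Those of 8q24.21 fell along chromosome 6 at 72150001, with steps of 9.29 and 8.28, against 1.24 in GM06990. Those of 2q35 fell on chromosome 3 at 34400001 (3.70 and 3.23, against 1.26 in GM06990) and those of the chromosome 18 region on chromosome 5 at 18200001 (3.57 and 3.22, against 1.33). In BT483 the chromosome 16 region had an edge on chromosome 12 at 125550001 (5.57 and 2.10), against 1.45 in GM06990, just under the limit of 1.5. These 5 edges, of 8 pairs of region and chromosome, lay within 2 Mb of a segment raised from that region alone. With all windows 2 did so. The segments were built from both replicates without windows high in GM06990, so the selection favoured such steps in replicate 2 and their absence in GM06990. That a junction that joins the region to the segment, sequence gaps left out, edge at the segment (5 of 8), lies behind these edges is an open hypothesis, which DNA sequence across the edges could test.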
